A study of Homo sapiens with 6 samples.

How the data were processed

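RNA-seq was measured in 6 libraries of human embryonic stem cells after 4 days of spontaneous differentiation in micropatterned tissue, 3 of the stress-high layer labelled primitive endoderm (PE) and 3 of the stress-low aggregate labelled epiblast (Epi). Per the labels' protocols, the aggregates were taken off with forceps before the remaining layer was scraped, RNA was isolated with the RNeasy Micro kit, libraries were made with the TruSeq RNA v2 kit, and single reads of 86 bp were sequenced on a NextSeq500. The kit does not mark strand, so reads of overlapping genes on opposite strands cannot be separated. The labels name 3 cell lines (HuES-8, H1:OCT4-GFP and I3) and give none for a library. Groups and replicate numbers came from the sample labels.

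The deposited table of estimated counts per gene holds RSEM expected counts, per the file headers, with alignment by Bowtie2 to hg19, per the submitters' processing notes, which give no versions and also name DESeq2 without a role. The deposited table of TPM comes from the same quantification, per the file headers, and the authors scaled it so that each library sums to the same total. TPM is relative within a library, so a gene's TPM falls when others rise. A deposited sheet pairs gene names with RefSeq transcripts. The tables hold 23686 genes, of which 28 have names that a spreadsheet had turned into dates, and these were left as they stand. Coordinates are not given, because the hg19 annotation was not used here. RSEM divides reads that fit several genes among them by an estimate, which leaves near-identical and overlapping genes uncertain. Comparisons with blastocyst data, which the design text mentions, were not analysed here.

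Estimated counts were rounded to whole numbers. Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM scaling, filterByExpr with a minimum count of 10, no covariates, Benjamini-Hochberg adjustment over 14789 genes, threshold 0.05). Fold changes are PE over Epi, and the SE is the absolute log2 fold change divided by the square root of F. Counts with an added minimum of a 2-fold change are given beside the others. The common biological coefficient of variation was 0.0671. Total counts ran from 9059393 to 17488263, so that 1 count was 0.0572 to 0.110 CPM. The 3 measures of depth and composition were compared by exact 2-sided permutation tests, for which 3 against 3 cannot go below p = 0.1.

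The design, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The 33 lists cover pluripotency, endoderm, mesoderm, trophectoderm, amnion, ectoderm, endothelium and blood, germ cells, YAP/TEAD and SRF targets, adhesion, signalling, metabolism, proliferation, p53, tissue handling and mitochondrially encoded RNAs, and were tested where at least 3 members passed the filter. The list test was camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), 2-sided and adjusted over the 32 lists tested, and it was repeated with an estimated correlation. Fry was run beside it. Members of lists overlap, so the lists are not independent. Named genes are the 4 stain genes (NANOG, POU5F1, GATA6 and SOX17), the 10 largest log2 fold changes per direction among 4380 candidates, and for each list its first 2 genes and up to 2 more with the smallest p. A candidate passed the threshold, had a mean of at least 20 TPM in the higher group and had TPM values that did not overlap between groups, and names of the LOC, orf and pseudogene type were left out. The rule gave 141 genes, of which a few are not reported here.

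The steps were tested on simulated counts for 14632 genes with the means and library sizes of these libraries. Of 50 genes changed at each size, 7 were recovered at 1.2-fold, 31 at 1.5-fold, 43 at 2-fold and 50 at 4-fold, and 12 of 14416 unchanged genes were called. A list of 20 genes changed by 1.5-fold had a camera adjusted p = 9.0e-41, and adjusted p = 0.00481 with an estimated correlation. None of 40 unchanged lists was called. The simulated genes varied independently of each other, so this cannot show how often camera calls lists of correlated genes. Far fewer genes were changed than the 56.5% that passed in these data.

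The alternatives were RLE and upper-quartile scaling, scaling without the 50 most abundant genes, no filter, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with at least 1 TPM in 3 samples, the replicate number as a block, and each replicate left out in turn. For lists they were the estimated correlation, log2(TPM + 1), the block, each replicate left out, and members held by only 1 list. Scalings for lists, thinning to the shallowest library and a test against a 2-fold change (glmTreat) were added after seeing the data. Gene families were also tested after their values were seen.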

Results

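RNA-seq measured gene expression in human embryonic stem cells, cultured pluripotent cells derived from early embryos, after 4 days of spontaneous differentiation in micropatterned tissue. The tissue region under high mechanical stress was a cell layer that stained for GATA6 and SOX17 and not for NANOG or OCT4, and the labels name it primitive endoderm (PE). The region under low stress was an aggregate with the opposite stains, named epiblast (Epi). There were 3 PE and 3 Epi libraries. The aggregate was lifted off with forceps and the layer was scraped off afterwards, so the way of collection went with the group. The labels put both fractions at over 95% homogeneous by immunofluorescence. Total estimated counts were 15196002, 14859090.1 and 17488263 in PE replicates 1, 2 and 3, and 14454048, 13277507 and 9059393 in Epi replicates 1, 2 and 3. Between 17669 and 18128 genes had counts in a library. The 10 most abundant genes took 4.54 ± 0.108% of counts in PE and 4.80 ± 0.0712% in Epi (mean ± SD, n = 3 each, exact 2-sided permutation p = 0.1, the smallest that 3 against 3 can give). The total counts also gave p = 0.1 in that exact test, and the numbers of genes detected gave p = 0.5. Across genes, which are not independent replicates, Pearson's correlation of log2 CPM was 0.989 to 0.992 within groups and 0.939 to 0.954 between them. No library was a copy of another of its group, since counts within groups differed by 2.06 to 9.85 times sampling noise (chi-square per degree of freedom). The labels list 3 stem cell lines without tying a library to a line, and do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which can be technical.

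The comparison of PE with Epi addresses whether the stress-low region expresses genes of the epiblast, the part of the blastocyst that forms the embryo, and the stress-high region those of primitive endoderm, which forms yolk sac endoderm. NANOG and POU5F1, which encodes OCT4, are transcription factors of pluripotency and were lower in PE. NANOG stood at 47.3 ± 6.10 TPM in PE and 187 ± 3.72 TPM in Epi (mean ± SD, n = 3 per group throughout). Its log2 fold change, PE over Epi throughout, was -2.0 ± 0.07 (SE; edgeR adjusted p = 5.9e-10). POU5F1 stood at 270.1 ± 68.4 TPM in PE and 2119 ± 97.1 TPM in Epi, a log2 fold change of -2.98 ± 0.12 (edgeR adjusted p = 9.4e-10). GATA6 and SOX17, endoderm transcription factors, were higher in PE by smaller steps. GATA6 measured 312 ± 29.3 TPM in PE and 201 ± 3.85 TPM in Epi, a log2 fold change of 0.63 ± 0.07 (edgeR adjusted p = 4.7e-06). SOX17 measured 306 ± 17.5 TPM in PE and 175 ± 17.7 TPM in Epi, a log2 fold change of 0.79 ± 0.08 (edgeR adjusted p = 1.7e-06). GATA6 RNA in Epi was thus at 64.2% of its PE level and SOX17 RNA at 57.2%, while NANOG RNA in PE was at 25.3% of its Epi level and POU5F1 RNA at 12.7%. The values of the 3 PE libraries did not overlap those of the 3 Epi libraries for any of these genes. The regions were told apart by these stains, so the direction of these RNAs checks the labels and is not an independent result.

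**Figure D1:**
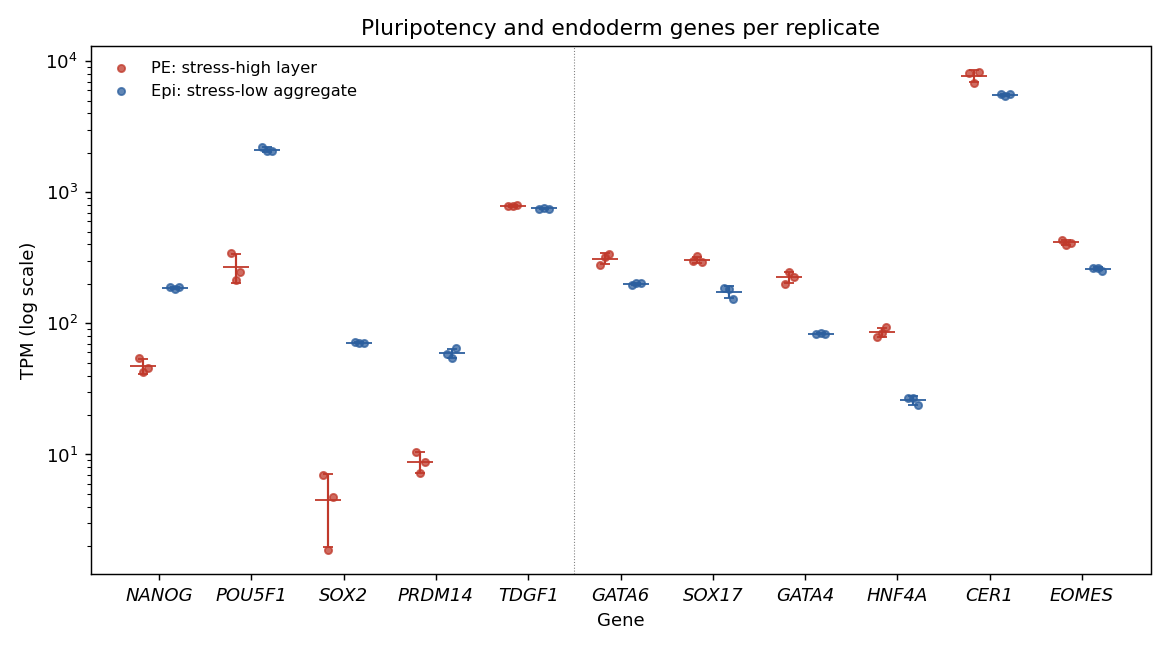
TPM on a log scale for pluripotency genes (left of the dotted line) and endoderm genes (right) in PE (red) and Epi (blue), where points are the 3 replicates, horizontal bars the mean and vertical bars the SD. POU5F1 lies at 270.1 TPM in PE against 2119 TPM in Epi, while CER1 lies at 7755 and 5563 TPM, the highest of the genes shown.

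Between the regions, 4152 of the 14789 genes tested were higher in PE and 4210 were higher in Epi at the adjusted p threshold of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), together 56.5% of the genes tested. With a change of at least 2-fold added, 634 genes were higher in PE and 1308 in Epi, so that 67.4% of the 2-fold changes were toward Epi. The TPM values of the groups did not overlap for 9216 genes, 62.3% of those tested, against 10% by chance for 3 against 3. The first principal component of log2 CPM held 80.0% of the variance and separated PE from Epi, and the next held 6.32%. With limma on log2(TPM + 1) the genes higher in PE by at least 2-fold numbered 405 and the genes higher in Epi by at least 2-fold 737. A test against a 2-fold change itself (edgeR glmTreat), chosen after seeing the data, gave 286 and 724.

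**Figure D2:**
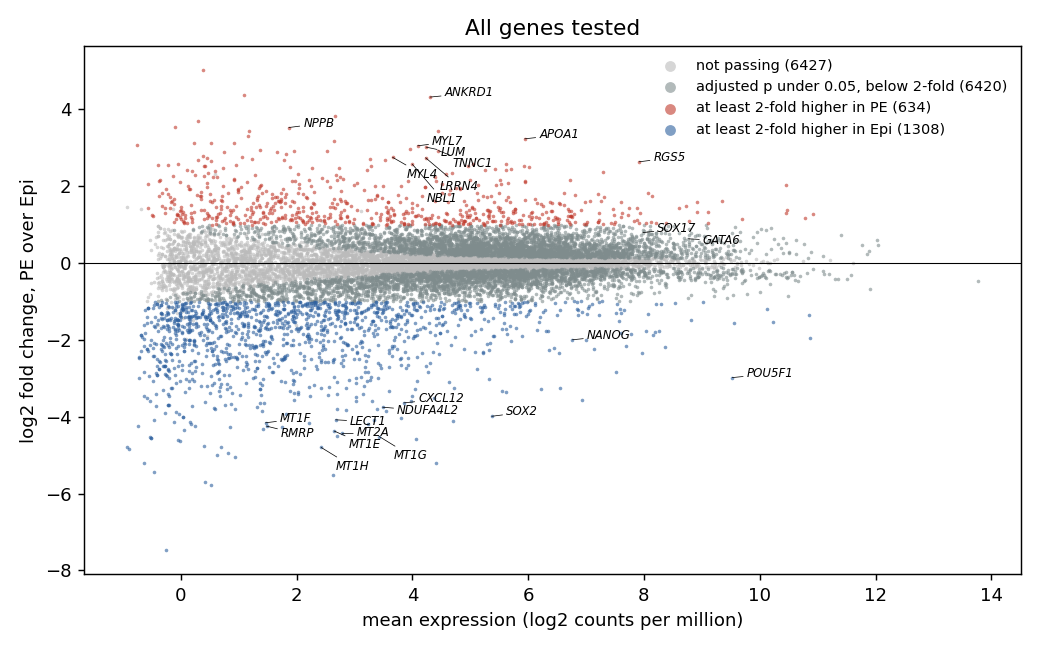
Log2 fold change of PE over Epi against mean expression in log2 CPM for the 14789 genes tested, with the stain genes and the largest abundant changes named. Red points are the 634 genes at least 2-fold higher in PE, blue points the 1308 at least 2-fold higher in Epi, dark grey points smaller changes past the threshold and light grey points genes that did not pass.

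Among genes with at least 20 TPM in the higher group, the largest increases in PE included several genes of heart muscle, APOA1 and LUM. ANKRD1, a stretch-responsive muscle gene and YAP/TEAD target, rose from 2.09 ± 0.556 TPM in Epi to 40.7 ± 4.23 TPM in PE, a log2 fold change of 4.32 ± 0.16 (edgeR adjusted p = 4.6e-10). NPPB, which encodes the B-type natriuretic peptide, rose by 3.53 ± 0.36 on the log2 scale (20.3 ± 5.11 against 1.77 ± 1.04 TPM, PE against Epi throughout). Its counts in Epi were few, 3, 11 and 5 in replicates 1, 2 and 3. The atrial myosin light chain genes MYL7 and MYL4 rose by 3.05 ± 0.13 (117 ± 2.78 against 13.7 ± 2.88 TPM) and 2.75 ± 0.15 (56.4 ± 4.71 against 8.46 ± 1.63 TPM). TNNC1, troponin C of heart and slow muscle, rose by 2.92 ± 0.12, to 126 ± 9.74 TPM in PE. APOA1, the main protein of high-density lipoprotein, measured 282 ± 26.9 against 29.99 ± 5.44 TPM (log2 fold change 3.23 ± 0.12, edgeR adjusted p = 5.9e-10). LUM, a matrix proteoglycan, rose by 3.02 ± 0.18, LRRN4 by 2.74 ± 0.11, and RGS5, a regulator of G-protein signalling, by 2.63 ± 0.08, to 155 ± 16.4 TPM in PE. NBL1, a secreted BMP antagonist, measured 28.8 ± 3.35 against 4.94 ± 4.96 TPM (log2 fold change 2.57 ± 0.49, edgeR adjusted p = 6.2e-04). NBL1 is uncertain because it can share reads with the readthrough gene C1orf151-NBL1 (52.1 ± 9.52 against 22.5 ± 7.12 TPM), it was listed at 0 in Epi replicate 1, and it did not pass with DESeq2 (adjusted p = 0.215, range over alternatives 8.5e-06 to 0.215). The log2 fold change of NBL1 was 1.89 without Epi replicate 1, 3.89 without Epi replicate 2 and 4.83 with limma-voom.

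Metallothionein genes, which encode small proteins that bind zinc and copper, held 5 of the 10 largest increases in Epi. MT1H measured 2.44 ± 0.655 against 69.1 ± 7.20 TPM (log2 fold change -4.80 ± 0.23, edgeR adjusted p = 2.9e-09). MT1G measured 6.00 ± 3.15 against 137 ± 18.4 TPM (-4.52 ± 0.23) and MT2A 3.90 ± 2.07 against 84.1 ± 12.2 TPM (-4.43 ± 0.25). MT1E measured 2.95 ± 1.75 against 60.1 ± 9.27 TPM (-4.37 ± 0.26) and MT1F 1.74 ± 1.49 against 31.5 ± 6.40 TPM (-4.16 ± 0.36). SOX2, a pluripotency and neural transcription factor, fell from 71.0 ± 0.700 TPM in Epi to 4.51 ± 2.55 TPM in PE, a log2 fold change of -3.99 ± 0.22 (edgeR adjusted p = 9.0e-09). LECT1, a secreted inhibitor of vessel growth from cartilage, measured -4.08 ± 0.18 on the log2 scale, NDUFA4L2, a hypoxia-induced mitochondrial gene, -3.75 ± 0.17, and the chemokine gene CXCL12 -3.64 ± 0.15. RMRP, the RNA part of the nuclease RNase MRP, measured 2.81 ± 0.767 against 53.6 ± 25.4 TPM (log2 fold change -4.24 ± 0.42, edgeR adjusted p = 2.5e-06). It rests on few counts, 3, 4 and 6 in PE replicates 1, 2 and 3, and 119, 58 and 31 in Epi replicates 1, 2 and 3. Metallothionein genes are near-identical copies of each other, so the split of reads among them is uncertain. Their counts in PE were also few, such as 9, 2 and 3 for MT1F and 6, 4 and 8 for MT1H in replicates 1, 2 and 3. The log2 fold change of MT1F was -5.04 without PE replicate 1.

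The fixed gene lists numbered 33, and 32 of them had at least 3 tested members. By camera with the preset correlation, 15 lists were higher in PE and 5 higher in Epi. With an estimated correlation 0 of 32 passed and 8 had an unadjusted p under 0.05. The immediate early list, chosen as a mark of tissue handling, was among the 15 higher in PE (median 0.74, camera adjusted p = 0.467 with an estimated correlation). By fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, 28 passed. The counts of members below are over all genes tested, and those adjusted over the list alone were the same for 29 of the 32 lists. Values with an error in brackets after a gene or its TPM are log2 fold changes ± SE.

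Pluripotency genes were mostly lower in PE. Of 25 epiblast and pluripotency genes, 17 were higher in Epi and 7 higher in PE, with a median log2 fold change of -1.01 (camera adjusted p = 8.6e-04, and adjusted p = 0.172 with an estimated correlation). On members held by no other list the median was -1.79. Beside NANOG and POU5F1, PRDM14, a repressor of differentiation genes, measured 8.79 ± 1.63 against 59.3 ± 4.97 TPM (log2 fold change -2.76 ± 0.11, edgeR adjusted p = 8.9e-10). The telomere protein gene TERF1 measured 65.4 ± 8.17 against 230.2 ± 2.23 TPM (log2 fold change -1.83 ± 0.07). Members that went the other way, named after their values were seen, included the NODAL pathway genes NODAL (0.46 ± 0.08), LEFTY1 (0.59 ± 0.09) and LEFTY2 (1.27 ± 0.08). TDGF1, the NODAL co-receptor, was the member that did not pass (791 ± 12.0 against 753 ± 9.04 TPM, edgeR adjusted p = 0.406). Of 14 primed pluripotency genes, 8 were higher in Epi, 3 higher in PE and 3 did not pass (median -0.83, camera adjusted p = 0.0268, and adjusted p = 0.323 with an estimated correlation). The surface protein gene THY1 fell to 13.4 ± 2.91 TPM in PE from 128 ± 3.42 TPM in Epi (log2 fold change -3.27 ± 0.11), and PTPRZ1 fell to 5.96 ± 1.92 from 66.6 ± 4.26 TPM (-3.57 ± 0.16). ZIC2 (237 ± 11.6 against 226 ± 3.68 TPM) and DUSP6 (44.5 ± 16.2 against 43.6 ± 3.34 TPM) did not pass. Naive pluripotency genes as a list did not pass (median 0.23, camera adjusted p = 0.231), with 4 of 10 higher in PE and 1 higher in Epi. DNMT3L and TBX3 of that list rose in PE by 3.17 ± 0.21 and 1.57 ± 0.08, and KLF17 and DPPA5 were below 1 TPM in both groups.

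Endoderm genes were higher in PE as a group and were also expressed in Epi. Of 21 primitive endoderm genes, 17 were higher in PE and 2 higher in Epi, with a median log2 fold change of 0.79 (camera adjusted p = 1.8e-07, and adjusted p = 0.172 with an estimated correlation). FRZB, a secreted WNT antagonist, measured 64.3 ± 2.25 against 15.1 ± 0.828 TPM (log2 fold change 2.07 ± 0.08, edgeR adjusted p = 5.9e-10). HNF4A, a transcription factor of liver, gut and visceral endoderm, measured 85.7 ± 7.20 against 26.0 ± 1.99 TPM (log2 fold change 1.76 ± 0.08, edgeR adjusted p = 2.0e-09). Of 10 tested visceral and yolk sac genes, 8 were higher in PE and 1 higher in Epi (median 1.16, camera adjusted p = 8.6e-04, and adjusted p = 0.244 with an estimated correlation). The other 8 of the 18 measured were too low to test, and the median level of all 18 was 0.450 TPM in PE and 1.43 TPM in Epi. Next to APOA1, the lipoprotein gene APOA2 measured 307 ± 44.6 against 92.0 ± 11.5 TPM (log2 fold change 1.72 ± 0.12). AFP (0.323 ± 0.303 against 2.22 ± 2.61 TPM) and TTR (0.113 ± 0.196 against 1.92 ± 2.66 TPM), secreted yolk sac proteins, were too low to test. They stood highest in Epi replicate 2, at 5.23 and 4.99 TPM. Of 19 definitive endoderm genes, 13 were higher in PE and 5 higher in Epi (median 0.47, camera adjusted p = 0.00622, and adjusted p = 0.244 with an estimated correlation). CER1, a secreted NODAL, BMP and WNT antagonist, reached 7755 ± 819.8 TPM in PE and 5563 ± 99.3 TPM in Epi (log2 fold change 0.47 ± 0.06, edgeR adjusted p = 1.7e-05). CXCR4, a chemokine receptor gene of migrating endoderm, measured 536 ± 13.4 against 308 ± 14.7 TPM (0.79 ± 0.05). GATA4 measured 224 ± 22.2 against 83.2 ± 0.929 TPM (1.42 ± 0.08) and STC1 229 ± 19.9 against 110.4 ± 1.48 TPM (1.04 ± 0.06). The visceral list did not pass without Epi replicate 3 (camera adjusted p = 0.0602, range over alternatives 1.1e-04 to 0.244). The definitive endoderm list shares 12 members with other lists and did not pass on its own members alone (camera adjusted p = 0.414, range 0.00210 to 0.414).

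**Figure D3:**
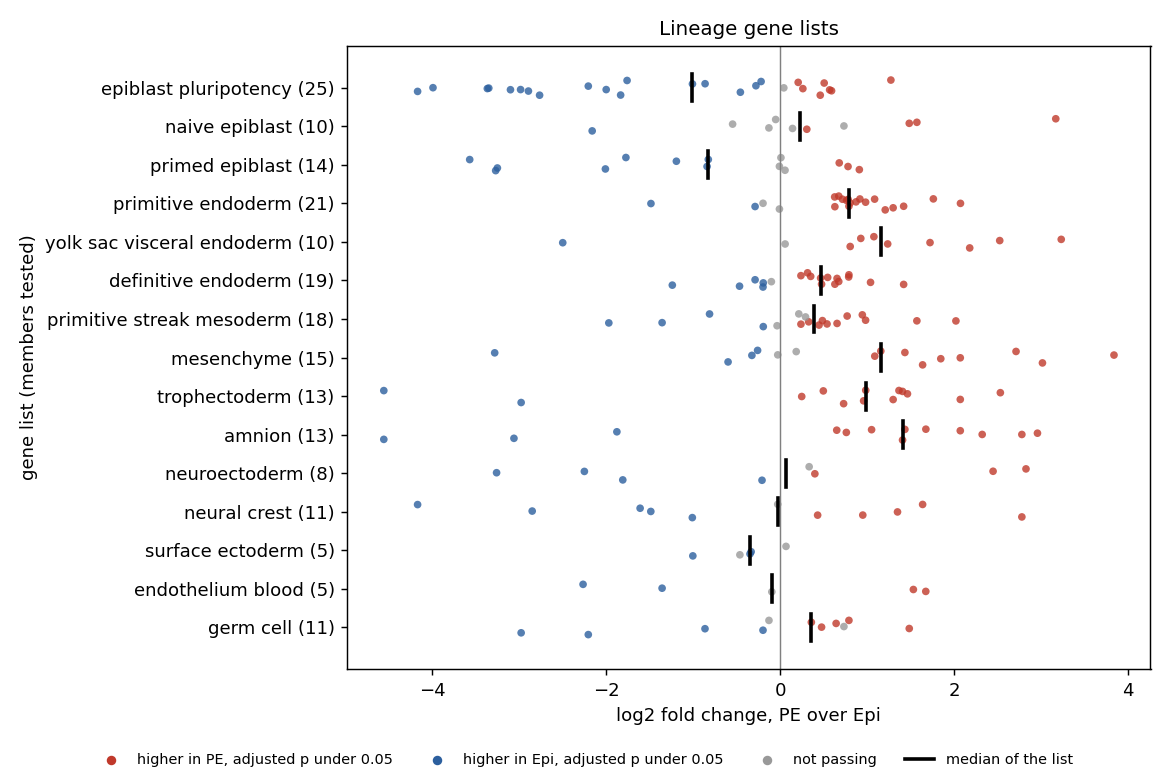
Log2 fold change of PE over Epi for the tested members of each lineage list, 1 point per gene, with the number tested in brackets and the list median as a black bar. The primitive endoderm median lies at 0.79 and the epiblast and pluripotency median at -1.01, and most lists hold members on both sides of 0.

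Mesoderm and mesenchyme lists leaned toward PE with members on both sides. Of 18 primitive streak and mesoderm genes, 11 were higher in PE and 4 higher in Epi (median 0.39, camera adjusted p = 0.0456, and adjusted p = 0.302 with an estimated correlation). The mesendoderm transcription factor genes MIXL1 (339 ± 8.97 against 174 ± 22.2 TPM, log2 fold change 0.95 ± 0.08) and EOMES (414 ± 17.6 against 261 ± 6.78 TPM, 0.66 ± 0.05) rose in PE. The brachyury gene T, of the early streak, fell by 1.97 on the log2 scale (1.16 ± 0.282 against 4.38 ± 0.388 TPM). Of 15 mesenchyme genes, 9 were higher in PE and 4 higher in Epi (median 1.16, camera adjusted p = 0.0179, and adjusted p = 0.244 with an estimated correlation). VIM, the intermediate filament vimentin, measured 1199 ± 40.1 against 533 ± 10.4 TPM (1.16 ± 0.04, edgeR adjusted p = 5.9e-10). PITX1, a hindlimb transcription factor, measured 10.3 ± 1.75 against 0.703 ± 0.0153 TPM (3.84 ± 0.23). The fibrillar collagen gene COL1A1 went toward Epi (23.3 ± 2.49 against 35.2 ± 3.98 TPM, -0.60 ± 0.10). COL3A1 was too low to test, at 3.30 TPM in Epi replicate 2, where AFP and TTR also stood highest, and at most 0.110 TPM elsewhere. The primitive streak list did not pass without PE replicate 1 (camera adjusted p = 0.0527), PE replicate 2 (0.0594) or Epi replicate 2 (0.0529), with log2(TPM + 1) (0.0554), or on members held by no other list (0.414; range over alternatives 0.0283 to 0.414). Its medians in that order were 0.38, 0.40, 0.36, 0.42 and 0.37. The mesenchyme list did not pass on members held by no other list (median 0.64, camera adjusted p = 0.431, range 0.00761 to 0.431).

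Trophectoderm and amnion lists were higher in PE, with a keratin and BMP pathway genes among the members that rose. Of 13 tested trophectoderm genes, 11 were higher in PE and 2 higher in Epi (median 0.99, mean 0.46, camera adjusted p = 7.9e-04, and adjusted p = 0.175 with an estimated correlation). The 2 higher in Epi changed by at least 2-fold, among them TFAP2C (1.15 ± 0.666 against 9.05 ± 0.335 TPM, log2 fold change -2.98 ± 0.25). KRT8, a keratin of simple epithelia in general, measured 2566 ± 127 against 986 ± 56.5 TPM (log2 fold change 1.37 ± 0.06, edgeR adjusted p = 1.3e-09). The phosphate transporter gene SLC34A2 measured 27.6 ± 2.86 against 4.71 ± 0.296 TPM (2.53 ± 0.11) and GATA3 56.8 ± 7.77 against 21.3 ± 1.15 TPM (1.41 ± 0.11). CDX2, a trophectoderm transcription factor, was at 0.0400 ± 0.0346 TPM in PE and 0.0233 ± 0.0404 TPM in Epi, and 12 of the 25 measured members were too low to test. Of 13 amnion genes, 10 were higher in PE and 3 higher in Epi (median 1.41, mean 0.59, camera adjusted p = 0.00581, and adjusted p = 0.172 with an estimated correlation). The 3 higher in Epi changed by at least 2-fold, among them HEY1 (0.847 ± 0.301 against 7.01 ± 0.225 TPM, -3.06 ± 0.22). The BMP target MSX2 (39.4 ± 1.90 against 7.71 ± 0.866 TPM, 2.32 ± 0.10) and the ligand gene BMP4 (56.0 ± 5.48 against 20.6 ± 0.974 TPM, 1.44 ± 0.09) rose in PE. ISL1 measured 2.64 ± 0.234 against 1.54 ± 0.0764 TPM (0.76 ± 0.20, edgeR adjusted p = 0.00591) and GABRP was too low to test. The amnion list shares 11 members with other lists and did not pass on the rest (median 0.91, camera adjusted p = 0.280, range over alternatives 0.00182 to 0.280), and ISL1 did not pass with DESeq2 (adjusted p = 0.0524, range 0.00536 to 0.0524).

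Lists of ectoderm, blood vessel and germ cell genes did not pass. Neuroectoderm genes had a median of 0.06 and a mean of -0.19 (3 of 8 higher in PE, 4 higher in Epi, camera adjusted p = 0.929). The eye and forebrain genes PAX6 (27.4 ± 2.16 against 5.01 ± 0.350 TPM, log2 fold change 2.45 ± 0.09) and LHX2 (2.83 ± 0.25) rose in PE. MAP2 of that list was higher in Epi (-3.26 ± 0.41) at under 1 TPM, and SOX1 was too low to test. Neural crest genes divided evenly, with 5 of 11 higher in each region (median -0.03, camera adjusted p = 0.751). FOXD3, also a pluripotency gene, fell in PE to 0.547 ± 0.271 from 10.1 ± 0.246 TPM (-4.17 ± 0.24) and so did ERBB3 (-1.01 ± 0.07). SOX10 rose (0.95 ± 0.14) and PAX3 was too low to test. Of 5 surface ectoderm genes, 3 were higher in Epi and 2 did not pass (median -0.35, camera adjusted p = 0.108). The epithelial regulator GRHL2 (-1.0 ± 0.09) and CDH3 (-0.35 ± 0.06) were among them, with TP63 and KRT5 too low to test. Endothelial and blood genes numbered 5 tested, 2 higher in each region (median -0.09, camera adjusted p = 0.733). The VEGF receptor genes FLT1 (5.78 ± 0.842 against 25.3 ± 1.59 TPM, -2.26 ± 0.13) and KDR (24.0 ± 6.33 against 60.9 ± 3.52 TPM, -1.36 ± 0.13) were higher in Epi, and PECAM1 and CDH5 were below 1 TPM in both groups. Of 11 germ cell genes, 5 were higher in PE (6 adjusted over the list alone) and 4 higher in Epi, with a median of 0.36 against a mean of -0.17 (camera adjusted p = 0.779). PRDM1 rose in PE (0.48 ± 0.07), TFAP2C (-2.98 ± 0.25) and PDPN (-0.86 ± 0.07) were higher in Epi, and NANOS3 was too low to test.

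Genes of the contractile cytoskeleton and basement membrane were higher in PE, the region labelled as stress-high. Of 21 actomyosin and SRF target genes, 16 were higher in PE and 3 higher in Epi (median 0.46, camera adjusted p = 7.9e-04, and adjusted p = 0.302 with an estimated correlation). MYL9, the regulatory light chain of non-muscle and smooth muscle myosin, measured 190.3 ± 15.6 against 43.1 ± 2.61 TPM (log2 fold change 2.13 ± 0.09, edgeR adjusted p = 1.2e-09). The tropomyosin gene TPM1 measured 329 ± 4.60 against 159 ± 7.29 TPM (1.06 ± 0.05). The actin-binding LIMA1 was higher in Epi (-1.03 ± 0.07) and ACTA2 was too low to test. Of 17 basement membrane genes, 13 were higher in PE and 4 higher in Epi (median 0.52, camera adjusted p = 0.00134, and adjusted p = 0.323 with an estimated correlation). Among these were the collagen IV genes COL4A1 (316 ± 10.02 against 182 ± 6.24 TPM, 0.78 ± 0.05) and COL4A2 (0.87 ± 0.05), SPARC (0.81 ± 0.04) and AGRN (1.07 ± 0.08). Of 21 YAP/TEAD targets, 11 were higher in PE (12 adjusted over the list alone) and 4 higher in Epi (median 0.52, camera adjusted p = 0.0336, and adjusted p = 0.467 with an estimated correlation). MYOF, a membrane repair gene, measured 84.8 ± 5.30 against 16.3 ± 1.01 TPM (2.37 ± 0.07, edgeR adjusted p = 1.0e-10), and ANKRD1 rose as given. The widely used targets CYR61 (102 ± 84.1 against 72.4 ± 32.8 TPM, edgeR adjusted p = 0.410) and CTGF (73.6 ± 47.5 against 57.4 ± 24.8 TPM, 0.456) did not pass in the main test. They passed higher in PE without PE replicate 1 (log2 fold changes 1.01 and 0.80, edgeR adjusted p = 0.00924 and 0.0193, ranges over alternatives 0.00924 to 0.870 and 0.0193 to 0.948). Without PE replicate 3 their log2 fold changes turned to -0.29 and -0.18 (edgeR adjusted p = 0.638 and 0.736). The YAP/TEAD list had a median of 0.80 without PE replicate 1 and did not pass without PE replicate 3 (camera adjusted p = 0.0637) or on members held by no other list (0.0745, range 0.0111 to 0.467). Basement membrane did not pass on such members (camera adjusted p = 0.173, range 3.7e-04 to 0.323). Immediate early genes, which respond to tissue handling, were also higher in PE (median 0.74, camera adjusted p = 0.00365, and adjusted p = 0.467 with an estimated correlation).

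The integrin, epithelial junction and mesenchymal transition lists did not pass and held members on both sides. Of 21 integrin and focal adhesion genes, 4 were higher in PE and 9 higher in Epi (median -0.22, camera adjusted p = 0.439). The fibronectin receptor gene ITGA5 (172 ± 3.60 against 95.7 ± 3.26 TPM, log2 fold change 0.83 ± 0.05) and PARVA (0.97 ± 0.07) rose in PE. ITGB1 (-0.38 ± 0.07) and the laminin receptor gene ITGA6 (14.8 ± 0.244 against 27.6 ± 1.03 TPM, -0.90 ± 0.07) were higher in Epi. Of 20 epithelial junction genes, 8 were higher in PE and 7 higher in Epi, with a median of 0.09 and a mean of -0.18 (camera adjusted p = 0.816). The E-cadherin gene CDH1 fell to 44.6 ± 3.55 TPM in PE from 158 ± 10.1 TPM in Epi (log2 fold change -1.84 ± 0.06, edgeR adjusted p = 3.7e-10). The claudin gene CLDN4 fell to 1.96 ± 0.508 from 23.8 ± 1.89 TPM (-3.58 ± 0.17), JUP, which encodes plakoglobin, rose (0.97 ± 0.07), and EPCAM did not pass (397 ± 13.4 against 362 ± 17.5 TPM, edgeR adjusted p = 0.0722). Mesenchymal transition genes had 8 of 15 members higher in PE and 4 higher in Epi (5 adjusted over the list alone), a median of 0.49 and a camera adjusted p = 0.138. The N-cadherin gene CDH2 (346 ± 13.5 against 244 ± 3.25 TPM, 0.49 ± 0.04) and the protease gene MMP14 (1.04 ± 0.05) rose in PE, and LOX, a collagen cross-linking enzyme gene, was higher in Epi (-2.74 ± 0.15).

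Target genes of BMP, WNT and NODAL signalling were higher in PE. Of 13 BMP targets, 11 were higher in PE and 2 did not pass (median 0.97, camera adjusted p = 7.5e-05, and adjusted p = 0.172 with an estimated correlation). MSX2 rose as given, and the secreted BMP modulator BMPER measured 32.0 ± 1.12 against 7.63 ± 0.715 TPM (log2 fold change 2.06 ± 0.08, edgeR adjusted p = 8.0e-10). The general BMP targets ID1 (210.1 ± 46.8 against 199 ± 10.6 TPM, edgeR adjusted p = 0.674) and ID2 (52.2 ± 6.15 against 50.2 ± 4.63 TPM, 0.672) were the members that did not pass. Of 14 WNT targets, 9 were higher in PE and 2 higher in Epi (median 1.0, camera adjusted p = 8.6e-04, and adjusted p = 0.172 with an estimated correlation). DKK1, a secreted WNT antagonist, measured 103 ± 8.65 against 17.1 ± 0.969 TPM (log2 fold change 2.57 ± 0.08, edgeR adjusted p = 2.5e-10). The R-spondin receptor gene LGR5 measured 81.2 ± 2.58 against 25.4 ± 1.30 TPM (1.67 ± 0.07) and AXIN2 50.1 ± 4.61 against 36.2 ± 1.13 TPM (0.45 ± 0.07), with LEF1 too low to test. Of 13 NODAL targets, 10 were higher in PE and 2 higher in Epi (median 0.59, camera adjusted p = 8.6e-04, and adjusted p = 0.172 with an estimated correlation). The NODAL antagonist gene LEFTY1 measured 2652 ± 417 TPM in PE and 1749 ± 58.3 TPM in Epi, and LEFTY2 2819 ± 324 TPM in PE and 1164 ± 29.7 TPM in Epi. FST, the activin antagonist follistatin, measured 118 ± 4.43 against 26.97 ± 1.37 TPM (2.11 ± 0.08, edgeR adjusted p = 4.6e-10). The NODAL list shares 8 members with other lists and did not pass on the rest, though their median was larger, at 1.17 (camera adjusted p = 0.0746, range over alternatives 3.1e-04 to 0.172).

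Notch targets were mostly higher in Epi, and FGF/ERK and retinoid lists did not pass. Of 9 Notch targets, 7 were higher in Epi and 2 higher in PE (median -1.83, camera adjusted p = 0.0456, and adjusted p = 0.244 with an estimated correlation). The Notch effector genes HES1 (11.1 ± 4.42 against 40.9 ± 7.43 TPM, log2 fold change -1.91 ± 0.21) and HEY1 (0.847 ± 0.301 against 7.01 ± 0.225 TPM, -3.06 ± 0.22) fell in PE. HEY2 (-2.56 ± 0.17) and the feedback gene NRARP (-1.83 ± 0.12) also fell. FGF/ERK targets had 5 of 15 members higher in PE and 6 higher in Epi, with a median of 0.01 and a mean of -0.19 (camera adjusted p = 0.779, direction Epi). ETV1 (-1.70 ± 0.10) and SPRY1 (-1.80 ± 0.12) of that list were higher in Epi, and DUSP6 and SPRY4 (62.6 ± 7.41 against 56.6 ± 4.96 TPM, edgeR adjusted p = 0.180) did not pass. Of 9 retinoid targets, 6 were higher in PE and 2 higher in Epi (median 0.57, camera adjusted p = 0.100). The retinoic acid hydroxylase gene CYP26A1 measured 726 ± 37.4 against 492 ± 15.4 TPM (0.55 ± 0.05) and HOXB2 rose in PE (2.76 ± 0.33), and STRA6 was higher in Epi (-0.92 ± 0.10). The Notch list did not pass without PE replicate 1 (camera adjusted p = 0.0522), PE replicate 2 (0.0553) or Epi replicate 2 (0.0529), with log2(TPM + 1) (0.0506) or upper-quartile scaling (0.0774), or on members held by no other list (0.173; range over alternatives 0.0313 to 0.244). Its medians in that order were -1.84, -1.67, -1.81, -1.03, -1.89 and -1.33. The retinoid list passed without Epi replicate 3 (camera adjusted p = 0.0472, range 0.0472 to 0.397).

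**Figure D4:**
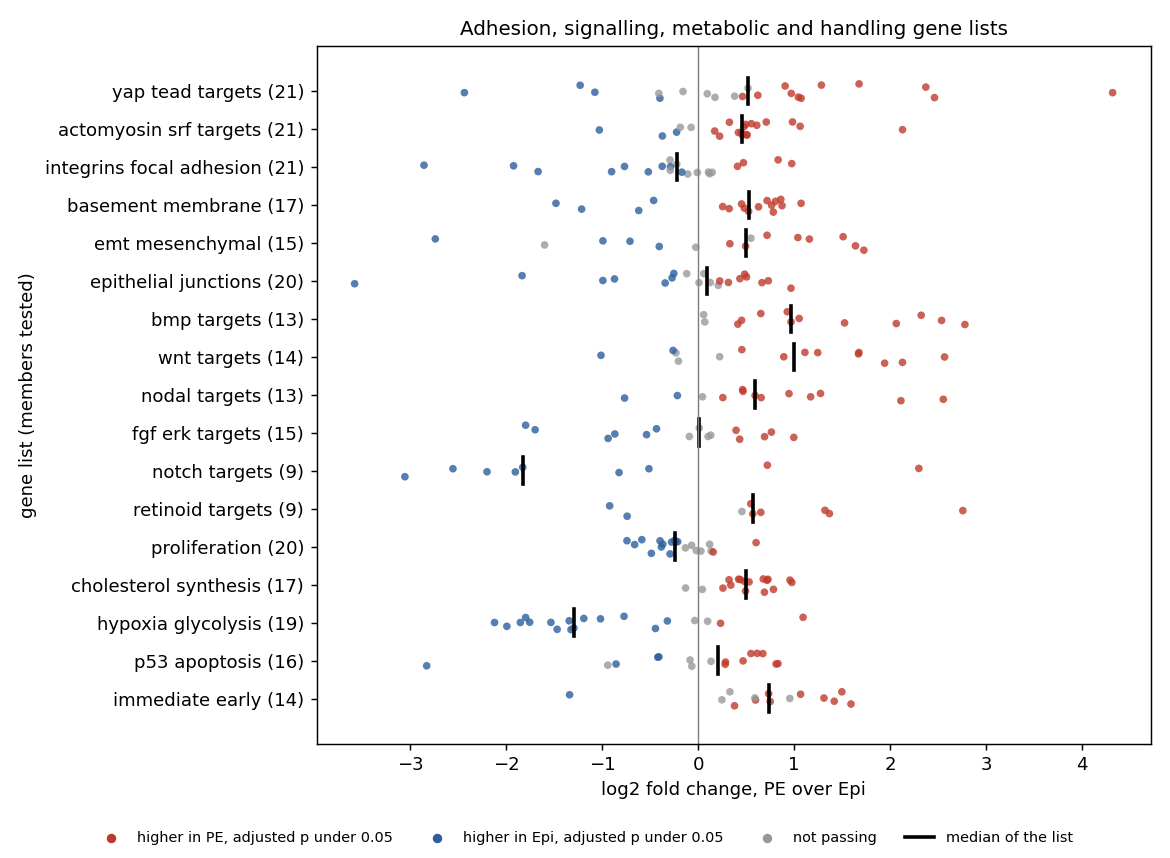
Log2 fold change of PE over Epi for the tested members of the adhesion, signalling, metabolic and handling lists, 1 point per gene, with the number tested in brackets and the list median as a black bar. The hypoxia and glycolysis median lies at -1.30, the Notch median at -1.83 and the WNT median at 1.00.

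Glycolytic and hypoxia-induced genes were higher in the Epi aggregate. Of 19 such genes, 15 were higher in Epi and 2 higher in PE (median -1.30, camera adjusted p = 2.4e-07, and adjusted p = 0.174 with an estimated correlation). PGK1, a glycolytic enzyme gene, measured 572 ± 68.0 against 1644 ± 41.8 TPM (log2 fold change -1.54 ± 0.06, edgeR adjusted p = 1.1e-09). The aldolase gene ALDOA measured 973 ± 26.8 against 2204 ± 84.1 TPM (-1.19 ± 0.05). The mitophagy gene BNIP3 measured 353 ± 31.01 against 969.7 ± 35.6 TPM (-1.47 ± 0.06) and VEGFA 73.1 ± 4.20 against 98.4 ± 3.79 TPM (-0.45 ± 0.06). Cell division genes were slightly higher in Epi, with 12 of 20 members higher in Epi and 2 higher in PE (median -0.24, camera adjusted p = 0.0114, and adjusted p = 0.244 with an estimated correlation). TOP2A (175 ± 24.3 against 275 ± 8.08 TPM, -0.66 ± 0.07), BUB1B (-0.74 ± 0.06) and CCNB2 (-0.59 ± 0.06) fell in PE. MKI67, a gene of cycling cells, did not pass (62.0 ± 7.65 against 55.9 ± 6.03 TPM, edgeR adjusted p = 0.199). Cholesterol synthesis genes rose together in PE, 15 of 17 passing higher in PE and 2 not passing (median 0.49, camera adjusted p = 7.4e-06, and adjusted p = 0.246 with an estimated correlation). The synthesis enzyme genes HMGCS1 and SQLE rose by 0.53 ± 0.07 and 0.72 ± 0.05 on the log2 scale.

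Immediate early genes, a list chosen because they rise when tissue is handled, were higher in the PE layer. Scraping and high stress both went with PE, so their parts in this cannot be told apart. Of 14 such genes, 9 were higher in PE and 1 higher in Epi (median 0.74, camera adjusted p = 0.00365, and adjusted p = 0.467 with an estimated correlation). The heat shock genes HSPA1A (137 ± 11.6 against 50.9 ± 3.56 TPM, log2 fold change 1.42 ± 0.08) and HSPA1B (125 ± 15.1 against 59.4 ± 5.59 TPM, 1.07 ± 0.09), near-identical copies whose split of reads is uncertain, rose in PE. FOS (61.2 ± 52.4 against 32.6 ± 16.01 TPM, edgeR adjusted p = 0.0968) and JUN (49.8 ± 31.3 against 40.2 ± 12.8 TPM, 0.410) did not pass in the main test. They passed higher in PE without PE replicate 1 (log2 fold changes 1.33 and 0.64, edgeR adjusted p = 0.00866 and 0.0447, ranges over alternatives 2.1e-04 to 0.929 and 0.0447 to 0.733). Without PE replicate 3 the log2 fold change of FOS turned to -0.03 and that of JUN to -0.31 (edgeR adjusted p = 0.929 and 0.232). FOS also passed without PE replicate 2 (edgeR adjusted p = 0.0307), without Epi replicate 3 (0.0477) and, with all libraries, without a filter on low counts (0.0327) and with the replicate number as a block (2.1e-04). Among p53 and apoptosis genes 8 of 16 were higher in PE and 4 higher in Epi, with a median of 0.21 and a mean of -0.06 (camera adjusted p = 0.682). The cell cycle inhibitor gene CDKN1A rose in PE (0.83 ± 0.13). The pro-apoptotic PMAIP1 fell from 375 ± 10.9 TPM in Epi to 53.1 ± 7.12 TPM in PE (-2.83 ± 0.08, edgeR adjusted p = 1.0e-10). RRM2B was higher in Epi (-0.86 ± 0.09), and MDM2 did not pass (39.97 ± 3.05 against 36.1 ± 1.10 TPM). The list of 9 mitochondrially encoded RNAs was not analysed here.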

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

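The list scalings, the thinning and the test against a 2-fold change were chosen after the result was seen. Of 124 tested named genes, 114 kept their side of the threshold under every alternative run, as did 11 of 32 lists, and 2 of the 4 gene counts stayed within 1.5 times. No named gene or list that passed as reported changed sign. Of those that did not pass, 7 genes (DUSP6, ID1, ID2, CYR61, CTGF, FOS and JUN) and 4 lists (naive, neural crest, endothelium and blood, and FGF/ERK) changed sign under an alternative. The estimated correlation ended all 20 list calls by camera, among them those of the epiblast and pluripotency list (median -1.01, adjusted p = 0.172) and of the primitive endoderm list (median 0.79, adjusted p = 0.172; ranges over alternatives 2.6e-05 to 0.172 and 1.8e-08 to 0.172). The medians are the same as reported, since that setting changes the test alone. For the WNT and amnion lists the estimated correlations (-0.0276 and -0.0339) were below the preset 0.01. A higher correlation among members thus does not account for the lost calls of these lists. In the simulation, whose genes varied independently, the same setting took the changed list from a camera adjusted p = 9.0e-41 to 0.00481. The setting thus weakens the test even without correlation, so a lost call alone does not show that members of a list correlate. With limma on log2(TPM + 1), the genes higher in PE by at least 2-fold numbered 405 and the genes higher in Epi by at least 2-fold 737, on a scale that understates the change of low genes, such as PITX1 (2.71), FOXD3 (-2.86) and HOXB2 (1.71). The test against a 2-fold change gave 286 and 724, as it asks that the change exceed 2-fold by more than its error. Leaving out 1 replicate at a time gave 3496 to 4366 genes higher in PE and 3695 to 4350 in Epi, or 601 to 704 and 1337 to 1451 with at least 2-fold. DESeq2 passed 7426 genes, of which 7256 also passed as reported, and counts thinned to the shallowest library passed 7298, of which 7107 did, so depth limits the number of calls. Upper-quartile scaling moved the median log2 fold change of all genes to -0.06 and the share of passing genes higher in PE from 49.7% to 42.4%. Among named genes, 15 combinations of a gene and an alternative gained a call and 2 lost it (NBL1 and ISL1 with DESeq2), and among lists 1 gained and 39 lost it. The cause was not tested beyond what each setting does by construction. EPCAM passed without PE replicate 1 (edgeR adjusted p = 0.0139, range 0.0139 to 0.320) and, with all libraries, with no filter (edgeR, 0.0438) and with limma on log2(TPM + 1) and log2(TPM + 0.1) (0.0426 and 0.0439). So did SPRY4, MKI67 and MDM2 without PE replicate 2 (edgeR adjusted p = 0.0377, 0.00914 and 0.00746, ranges 0.0377 to 0.556, 0.00914 to 0.616 and 0.00746 to 0.305).

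The replicate numbers were not taken as pairs, since libraries of the same number in both groups had deviations from their group means that correlated at 0.03, -0.03 and 0.06 across genes. With the replicate block, the genes higher in PE numbered 4183 and the genes higher in Epi 4252. The genes higher in PE by at least 2-fold then numbered 630 and the genes higher in Epi by at least 2-fold 1320. The replicate block changed no list call, and of the named genes only FOS changed its call, passing higher in PE (log2 fold change 0.73, edgeR adjusted p = 2.1e-04, range 2.1e-04 to 0.929). In both groups, replicate 3 had the highest TPM of FOS, JUN, CYR61 and CTGF and replicate 1 the lowest, which was noticed after the values were seen. Of 6 libraries, 3 correlated best with their own number, each among 3 candidates. With no correlation between groups above 0.0593, this count is little evidence of pairing.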

Other observations

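The gene families in this part, the tests of carry-over between the fractions and the test of summed metallothionein levels were chosen after the result was seen. S100 genes, which encode small calcium-binding proteins, were higher in PE, 7 of 9 tested (6 under upper-quartile scaling), with a median log2 fold change of 0.92 (camera adjusted p = 4.5e-05 over 10 families, and adjusted p = 0.187 with an estimated correlation). S100A10 measured 917 ± 34.8 TPM in PE and 256 ± 8.92 TPM in Epi (mean ± SD, n = 3; log2 fold change 1.83 ± 0.06), S100A13 481 ± 17.7 against 182 ± 8.01 TPM (1.36 ± 0.07), S100A16 367 ± 49.9 against 81.6 ± 2.74 TPM (2.16 ± 0.10) and S100A14 119.7 ± 21.0 against 19.9 ± 3.50 TPM (2.57 ± 0.15). Ribosomal protein genes moved the other way by small steps, 69 of 80 tested higher in Epi (68 to 71 under other scalings), with a median of -0.29 (camera adjusted p = 2.2e-13, and adjusted p = 0.133 with an estimated correlation). RPL3 stood at 3812 ± 103 TPM in PE and 5061 ± 93.8 TPM in Epi (-0.42 ± 0.04). Of 39 measured HOX genes, which pattern the body axis, 3 could be tested and were higher in PE at low levels (median 2.76, camera adjusted p = 0.0344, and adjusted p = 0.187 with an estimated correlation). HOXB2 measured 4.49 ± 0.747 against 0.690 ± 0.346 TPM, HOXB3 1.77 ± 0.707 against 0.203 ± 0.0987 TPM and HOXD13 1.40 ± 0.361 against 0.360 ± 0.0608 TPM.

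Genes of gut and liver epithelium were a mixed group, 4 of 8 tested higher in PE and 2 higher in Epi (median 1.28, camera adjusted p = 0.165). VIL1, an actin-bundling protein of microvilli, measured 59.5 ± 5.93 against 13.1 ± 0.583 TPM (2.17 ± 0.10), PDZK1, a scaffold of the brush border, 42.0 ± 2.21 against 10.6 ± 0.413 TPM (1.96 ± 0.09) and the protease gene TMPRSS2 34.96 ± 1.24 against 7.86 ± 0.938 TPM (2.15 ± 0.10), all higher in PE. CYP2S1 (13.5 ± 0.898 against 56.8 ± 1.48 TPM, -2.08 ± 0.08) and the glypican gene GPC3 (8.84 ± 0.435 against 28.1 ± 0.567 TPM, -1.69 ± 0.09) were higher in Epi. Zinc finger genes named ZNF did not pass as a family (147 of 484 higher in Epi, 76 higher in PE, median -0.13, camera adjusted p = 0.0809), nor did histone genes (4 of 12 higher in Epi, adjusted p = 0.376) or protocadherin beta genes (2 of 13 higher in Epi, adjusted p = 0.420).

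With 6 samples there are 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, passed 8362 genes by edgeR, and the highest of the other splits passed 0. Every other split puts PE and Epi libraries into both groups, so the difference between the regions counts as spread within groups. Few genes can then pass, and the contrast with the real split is no measure of chance. At an unadjusted p under 0.05 the real split had 9022 genes and the highest of the others 243. With at least a 2-fold change the real split passed 1942 and the highest other 0 by edgeR, and of lists by camera 20 and 10.

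The 17 primitive endoderm genes that passed higher in PE, GATA6 and SOX17 among them, stood in Epi at a median of 54.2% of their PE level (23.5% to 64.3%), although the aggregate was unstained for GATA6 and SOX17. Cells of the layer carried over into the aggregate would bring all abundant RNAs of the layer at that share, yet 31 of 7094 abundant genes had a ratio of the highest Epi to the lowest PE library under 27.1%, down to 7.20% for ANKRD1, 13.9% for APOA1 and 14.9% for MYL7, which argues against carry-over as the whole source. In the other direction, the 17 pluripotency genes chosen because they passed higher in Epi stood in PE at a median of 21.3% of their Epi level (5.42% to 86.9%). Carried-over cells of the aggregate would bring LECT1 and SOX2 at the same share, but their highest PE over lowest Epi ratios were 6.18% and 9.89%. That argues against carry-over as the whole source for members at or above the median, such as NANOG (25.3%) and TERF1 (28.4%). POU5F1 (12.7%) and PRDM14 (14.8%) lay under the median but by their means above both ratios. For members near or below those ratios, such as FOXD3 (5.42%), carry-over of the aggregate cannot be told apart from expression in the layer. In this direction 7 genes lay under 10.7%, short of the 10 set for excluding it, and 4 of them were metallothionein genes. That count rests on the choice of members, since all 25 tested had a median of 50.6%, with 37 genes under 25.3%. Endoderm RNA made by cells of the aggregate may account for the first pattern as a hypothesis, and a smaller share of carried-over cells stays open.

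Metallothionein genes had the largest decreases named in PE, with all 6 tested higher in Epi under every scaling run (median -4.40, camera adjusted p = 3.8e-05, and adjusted p = 0.187 with an estimated correlation). The family was picked for its members among the largest changes, so these p-values restate that and add no support. A poorer yield of short transcripts in PE would lower other genes of that length, but 30 such genes had a median log2 fold change of -0.094 (95% bootstrap interval -0.22 to 0.09). Reads moved between near-identical copies would leave their sum unchanged, but the summed TPM of the 12 measured was 24.6 ± 11.9 in PE and 468 ± 22.1 in Epi, 19.0-fold higher in Epi (log2 ratio -4.25). No biological explanation was tested, and the way of collection went with the group.

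MYL7, TNNC1, MYL4 and NPPB, genes of heart muscle, were among the largest increases in PE. A heart muscle-like program would raise other heart genes too, and the 8 others tested had a median log2 fold change of 0.076 (95% bootstrap interval -2.17 to 1.65). NKX2-5 (3.70 ± 0.43), MYOCD (1.65 ± 0.20) and TTN (1.58 ± 0.09) rose in PE, while RYR2 (-2.51 ± 0.21), ACTN2 (-2.17 ± 0.35) and TNNI3 (-0.81 ± 0.17) fell. ACTC1 (4.55 ± 0.556 against 4.39 ± 0.738 TPM) and TNNI1 did not pass. The rest of the 18 such genes measured were too low to test. Of these, TNNT2, MYH6, MYH7, MYL2, MYL3, TBX5, CSRP3 and PLN had means below 1 TPM in both groups. NPPA (1.53 ± 0.748 against 0.490 ± 0.166 TPM) and BMP10 (0.483 ± 0.257 against 0 TPM) were higher in PE without overlap. A response of stretch and YAP/TEAD targets alone could raise the 4 genes with few others, and 3 of the 8 were higher in PE. The YAP/TEAD list holds neither the 4 genes nor any of the 18, so it cannot separate such targets from the rest. These explanations cannot be told apart, since the members went both ways, most at low levels.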
